A study of Drosophila melanogaster with 2 samples.

How the data were processed

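ChIP-seq of a GFP-tagged CG9817 (CG43347) was analysed from peak lists of 2 biological replicates, numbered 1 and 3, of whole embryos aged 10 to 24 h. Chromatin was sonicated to fragments of 200 to 800 bp, per the labels' protocols. The samples formed 1 group, so no groups were compared. Each deposited list gives intervals on release 6 (dm6) with a summit, and per the deposited notes the peaks were derived from each alignment together with a control. The signal of each peak is the value the authors deposited for it, on a scale that the sources used here do not define. It was used only to rank peaks within a list, except in 1 Pearson correlation on log2 values. The −log10 q value deposited by the authors beside each peak ran from 2.45 to 3.81 in the IDR-thresholded list, where 3218 of 5038 peaks shared the highest value, so it was not used for ranking. The peak caller and the version of the IDR step are not given in the sources used here. Control libraries and reads were not analysed here, and with peaks alone the depth of each replicate is unknown. Each full list holds exactly 30000 peaks, so its length carries no information on depth.

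Genes, transcripts and TSSs came from Ensembl release 115 (BDGP 6.54), with 18164 genes, 13945 of them protein-coding, and 23581 TSSs on the 6 major arms (134 Mb). Sequence came from the release 6 assembly. Overlaps and tests were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Coordinates are 1-based. The following choices were made before the data were examined, unless stated otherwise. A promoter peak had its summit within 500 bp of a TSS. A summit counted once, in the order TSS region, 5' UTR, coding sequence, 3' UTR, other exon, intron and intergenic. Replicates were compared at 50% reciprocal overlap in lists of the 5038 strongest peaks, with chance taken from 1000 circular shifts. Promoter share and classes were compared with 1000 random placements of the summits on their own arm. Arms were tested with two-sided exact binomial tests against their share of the sequence.

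Gene lists (20) were tested with two-sided Fisher's exact tests against all other protein-coding genes, and 241 of 246 members listed by name were matched to the annotation. Motifs (26) and all 7-mers were tested with two-sided exact sign tests on windows of 201 bp at the summit against flanks 600 bp away. The flank of each pair was drawn at random, while the printed flank percent is the mean of both sides. The mean signal rank of promoter and other peaks was compared through 100000 permutations of promoter status, and the 4 parts of the ranking were described without a test. P-values within a family were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Intervals are 95% Wilson intervals unless stated otherwise. They cover counting error over peaks or genes, which are not replicates, and the p-values describe peak lists from 2 biological replicates of 1 group.

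Named genes followed a fixed rule. It covered the tagged gene, the 15 strongest IDR-thresholded peaks with the nearest coding gene, and the 5 strongest peaks over 5 kb from any TSS. It also covered up to 4 members, by signal, of each list past the threshold and of the Hox, insulator and neural progenitor lists. Neighbouring genes named beside these peaks follow from their positions. The 10 named 7-mers were those with the largest ratio among 7-mers past the threshold and present in at least 2% of summit windows.

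Alternatives set beforehand were a stricter list (the stronger 2519 peaks), TSS distances of 250 and 1000 bp, a shared peak defined by an overlap of at least 1 bp or by summits within 100 bp, other windows, flanks and controls, permutation of lists within strata of TSS number, 1 gene per peak, and leaving out each replicate. With a replicate left out, the 5038 strongest peaks of the other took the place of the IDR-thresholded list. Further alternatives were chosen after the data were seen. They were the pooled peaks outside the IDR-thresholded list as background, the control matched on GC content and TSS distance for motifs and for 7-mers, 1 gene per peak for divergent promoters, lists without divergent pairs, classes among summits outside TSS regions (the observed number drawn from each random placement), and, for the arms, all 30000 peaks of each replicate and the pooled peaks outside the IDR-thresholded list. The GC values, gene biotypes, promoter shares of each replicate by list size, promoter peaks against other peaks for each sequence, and further gene families were also examined only after the data were seen.

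The tests of promoter share, replicate overlap, gene lists, motifs and 7-mers were run on simulated data, and the other tests were not. A planted promoter share of 57.3% was found as 57.4%, and 1 of 20 random lists was called. A planted overlap of 59.4% was found as 59.9%. Planted gene lists were called in 20, 18 and 20 of 20 runs (cytoplasmic ribosomal, insulator, odorant and gustatory), with 3 of 340 unplanted tests called. Of the 26 motifs 0 were called on random summits. With 1 site planted, both motifs and both 7-mers that it holds were called. In addition, 3 unrelated 7-mers of 8192 were called. These summits were placed at random, without the lower GC content that real summits had, so the runs do not give the rate of false calls there.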

Results

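Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Drosophila melanogaster embryos aged 10 to 24 h. The transgenic line carried the protein of the gene CG43347, labelled with its older name CG9817, fused at its C-terminus to green fluorescent protein (GFP). The precipitation used an antibody against GFP, per the labels' description. There were 2 samples in 1 group, biological replicates 1 and 3. Each replicate had a list of 30000 peaks, as did the list called on both replicates together. A list of 5038 peaks, thresholded by the irreproducible discovery rate (IDR), was the basis of the genomic comparisons. It consisted of the 5038 strongest peaks of the pooled list. Its peaks had a median width of 350 bp and covered 1.43 Mb, or 1.07% of the 6 major chromosome arms in the dm6 assembly. The read totals behind the lists were not used here, so the depth of each replicate is unknown. No group without the tagged protein was analysed here.

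Whether the replicates found the same sites was examined at equal list length. Of the 5038 strongest peaks of replicate 1, 3067 (60.9%, 95% Wilson interval 59.5 to 62.2) shared at least 50% of their length reciprocally with one of the 5038 strongest of replicate 3. Circular shifts of replicate 3 along the arms gave 0.840% ± 0.132 (SD over 1000 shifts), a 72.5-fold difference (one-sided permutation p = 0.001, the smallest these shifts can give). With an overlap of at least 1 bp 75.5% were shared, 35.1-fold over chance, with summits within 100 bp 72.6%, 95.4-fold, and among the stronger 2519 peaks 64.8%, 206-fold. The shared portion was 79.8% among the 500 strongest peaks and 42.3% among all 30000. The strongest peak of both lists was the same, 96 bp upstream of CG14100 on 3L, and the peak upstream of mRpL41, which encodes a protein of the mitochondrial ribosome, ranked 2 in both. Of the IDR-thresholded peaks, 3990 (79.2%) had a counterpart in the full list of each replicate. Across those 3990 peaks the authors' signal values had a Spearman rho of 0.729 (bootstrap SD 0.00933) and a Pearson r of 0.819 on the log2 scale, across peaks, which are not independent replicates. These peaks came from the strongest 5038 of the pooled list, to which the same 2 replicates contributed, and had to be present in both. That selection by itself can change both coefficients.

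The replicates differed in where their peaks lay. Among the 5038 strongest peaks, 58.5% (2949) of replicate 1 and 48.6% (2449) of replicate 3 had a summit within 500 bp of an annotated transcription start site (TSS), a difference of 9.92 percentage points (Fisher's exact test, p = 1.94e-23, adjusted over 7 list sizes 3.39e-23). Peaks among the strongest 5038 of a replicate without a match by the reciprocal overlap above in the other's strongest 5038 are called that replicate alone. They lay near a TSS in 60.3% of 1971 cases for replicate 1 alone, against 35.5% of 1967 for replicate 3 alone (Fisher's exact test, p = 2.27e-55). With an overlap of at least 1 bp, 75.5% of the replicate 1 list was shared, against 60.9% by reciprocal overlap. In counts, these were 3806 and 3067 of the 5038 peaks. Many of the 1971 peaks of replicate 1 alone thus still overlapped a peak of the replicate 3 list. No such count was made for replicate 3 alone, whose peaks may do so too. Of the peaks of replicate 1 alone and replicate 3 alone, 45.7% and 50.6% were present in the full list of the other replicate. The comparison is between 2 libraries, and its p-values count peaks, not embryos. The test on the 5038 strongest peaks also treats the 2 lists as independent, though 60.9% of the peaks were shared, so its p-value is not exact.

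**Figure D1:**
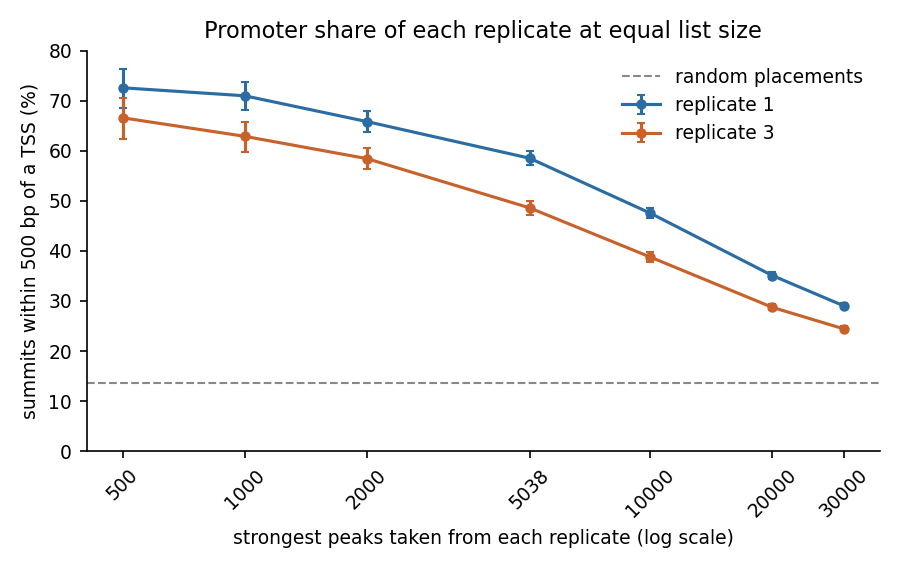
Percent of peak summits within 500 bp of a TSS (vertical axis) among the strongest 500 to 30000 peaks of each replicate (horizontal axis, log scale); bars are 95% Wilson intervals and the dashed line is the mean of random placements of the IDR-thresholded peaks, 13.6%. Replicate 1 lay above replicate 3 at each of the 7 list sizes, with 72.6% against 66.6% among the strongest 500 and 29.0% against 24.4% among all 30000.

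To place the tagged protein on the genome, each summit of the IDR-thresholded list was assigned to 1 annotated class. Start sites held 2626 of the 5038 summits (52.1%, 50.7 to 53.5), against 13.6% ± 0.506 (SD) in 1000 random placements on the same arms, a 3.84-fold difference (one-sided permutation p = 0.001, the smallest possible). Against the 24962 pooled peaks outside the IDR-thresholded list, a background chosen after the data were seen, of which 20.9% (20.4 to 21.4) lay at start sites, the difference was 2.50-fold. Coding sequence away from start sites held 9 summits (0.179%, 0.0940 to 0.339), against 13.7% ± 0.496 at random. As a share of all summits, 3' UTRs held 43 (0.854% against 4.44%), 5' UTRs 20 (0.397% against 0.782%), other exons 41 (0.814% against 0.810%), introns 1707 (33.9% against 39.5%) and intergenic sequence 592 (11.8% against 27.1%). A larger share at start sites lowers every other share, so the classes were also compared among the 2412 summits outside TSS regions, a setting chosen after the data were seen. There introns held 70.8% (68.9 to 72.6) against 45.8% ± 1.03 at random and other exons 1.70% (1.26 to 2.30) against 0.942% ± 0.207, both above random. Coding sequence (0.373% against 15.9%), 3' UTRs (1.78% against 5.15%) and intergenic sequence (24.5% against 31.4%) stayed below random, and 5' UTRs did not differ past the threshold (0.829% against 0.910%, two-sided permutation p = 0.779). Two-sided permutation p was 0.00400 for other exons and 0.002, the smallest the placements can give, for the remaining 4 classes. Of all IDR-thresholded summits, 1758 (34.9%) lay between 500 bp and 5 kb from the nearest TSS and 654 (13.0%) lay over 5 kb away.

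**Figure D2:**
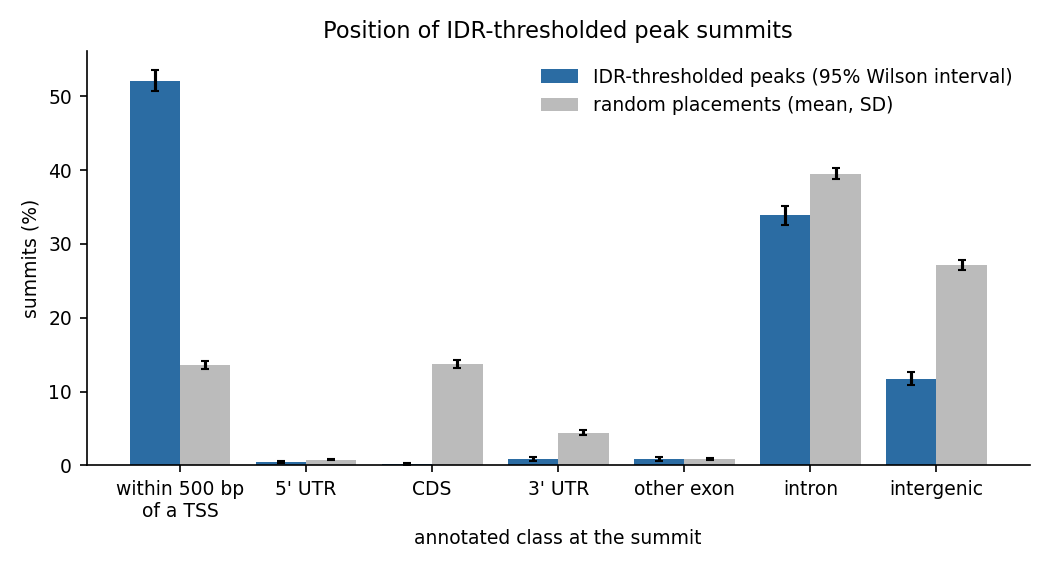
Percent of the 5038 IDR-thresholded summits in each annotated class (blue, 95% Wilson intervals) and the mean of 1000 random placements (grey, SD). The class within 500 bp of a TSS held 52.1% of summits against 13.6% at random, and coding sequence (CDS) held 0.179% against 13.7%.

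The chromosome arms were not covered evenly. Chromosome 4, the small arm rich in heterochromatin, held 6 peaks where its length predicted 50.7, a ratio of 0.118 (exact binomial test, adjusted p = 2.44e-14 over 6 arms). The ratio was 0.0788 without replicate 1 and 0.276 without replicate 3. The X chromosome had 41.5 peaks per Mb (39.0 to 44.2, exact Poisson interval, adjusted p = 0.00227) and 2L had 40.6 (38.0 to 43.2, adjusted p = 0.0224), both above their share of the sequence. Neither call held with the stronger 2519 peaks (adjusted p = 0.0784 for X and 0.179 for 2L, exact binomial test) or without replicate 3 (0.0999 and 0.193), and in the full lists of 30000 peaks, examined after the data were seen, X lay below its share (ratios 0.879 for replicate 1 and 0.826 for replicate 3). Arm 3L lay below its share, with 35.1 peaks per Mb (33.0 to 37.4, exact binomial test, adjusted p = 0.0232). That call did not hold with the stronger 2519 peaks (0.179), without replicate 1 (0.0658) or without replicate 3 (0.174), and 3L lay above its share in the full lists (ratios 1.02 and 1.07). Arms 2R (35.7, adjusted p = 0.105) and 3R (37.7, adjusted p = 0.974) did not pass the threshold of the same exact test.

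A promoter peak, meaning an IDR-thresholded summit within 500 bp of a TSS, was present at 3309 of 13945 protein-coding genes (23.7%). The median summit lay 135 bp upstream of the TSS (quartiles 219 and 75 bp upstream), and 91.0% of these genes had the summit upstream. Genes for tRNAs had a summit near their TSS in 18 of 290 cases (6.21%, 3.96 to 9.60) those for snoRNAs in 12 of 269 (4.46%, 2.57 to 7.63), those for snRNAs in 6 of 32 (18.8%, 8.89 to 35.3) and other noncoding genes in 210 of 3261 (6.44%, 5.65 to 7.33). Where 1 peak was given to the gene with the nearest TSS alone, 2339 protein-coding genes had one.

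Of the 15 strongest peaks, 10 lay within 500 bp of a TSS. The strongest, with a signal of 11419, spanned 19590408 to 19590818 on 3L, with its summit 96 bp upstream of CG14100 in intergenic sequence. The next, with a signal of 8221, spanned 15217576 to 15217989 on 2R, with its summit 137 bp upstream of mRpL41. The peak at 15229347 to 15229717 on 3R (signal 5586) lay between the divergent genes Art3, which encodes an arginine methyltransferase, and mRpS10, which encodes another mitochondrial ribosomal protein, 119 and 138 bp upstream of their TSSs. On the X chromosome, the peak at 2703706 to 2704072 (signal 5024) lay 42 bp upstream of Ugalt, the gene of a UDP-galactose transporter. The peak at 2137190 to 2137539 on the same chromosome (signal 4844) lay in an intron of the Polycomb group gene ph-p, 488 bp upstream of a TSS of that gene. Other promoter peaks among the 15 were at CG5611 and Mtl, a gene for a Rac-like GTPase (27635978 to 27636353 on 3R, signal 4568), at Tcs5 and CHMP2B (5139328 to 5139673 on 3L, signal 4345), at Pal1 and Pdrg1 (9959715 to 9960117 on 2R, signal 3872), and at eIF6, which encodes a factor of ribosome biogenesis (23850230 to 23850570 on 2R, signal 4047).

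The remaining strong peaks lay away from coding start sites. The peak at 480904 to 481274 on 2L (signal 4994) lay in an intron of ush, a cofactor of GATA factors, 1410 bp upstream of the transcription factor gene cbt. Introns also held the peaks at CG11050 (6612527 to 6612894 on 2L, signal 5795, 1027 bp downstream of the TSS), at CG9663 (3301955 to 3302590 on 2L, signal 4177, 945 bp downstream) and at CG32772 (4910175 to 4910567 on X, signal 3957, 1261 bp downstream). An intron of Trl, which encodes the GAGA factor, held the peak at 14759307 to 14759717 on 3L (signal 3871), 1537 bp upstream of its nearest Trl TSS. The peak at 12750867 to 12751610 on X (signal 4019) lay in an exon of the noncoding gene lncRNA:Vinr, 5081 bp from the TSS of CG4004, the nearest coding gene, and 469 bp from that of the noncoding gene lncRNA:CR44619. The 5 strongest peaks over 5 kb from any TSS had CG13323 (13035181 to 13035486 on 2R, intergenic, signal 2367), Hr3 (10219902 to 10220236 on 2R, signal 1950), CG16753 (3060645 to 3060937 on 3L, signal 1771), tara (16236783 to 16237112 on 3R, signal 1588) and Gug (8458169 to 8458486 on 3L, signal 1537) as nearest coding genes. Of these, the peaks at the nuclear receptor gene Hr3, at tara and at the corepressor gene Gug lay in introns of the named gene, and the peak nearest to CG16753 lay in an intron of CG32486.

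Genes of cytoplasmic and of mitochondrial ribosomal proteins carried promoter peaks more often than other coding genes. Among cytoplasmic ribosomal protein genes, 70 of 93 had one (75.3%, 65.6 to 82.9, against 23.4% of other genes, Fisher's exact test, adjusted p = 1.93e-24 over 20 lists). The strongest were at RpS27 (25247366 to 25247752 on 3R, signal 1957), RpL34b (9401152 to 9401565 on 3R, signal 1684), RpL7 (10200885 to 10201168 on 2L, signal 1474) and RpL23A (1668608 to 1668895 on 3L, signal 1163). Among mitochondrial ribosomal protein genes, 39 of 73 had one (53.4%, 42.1 to 64.4, Fisher's exact test, adjusted p = 2.10e-07), among them mRpL41 and mRpS10 above, mRpS23 (13835295 to 13835627 on 2L, signal 3009) and mRpL23 (2373441 to 2373782 on 3L, signal 2674). The mitochondrial list did not pass when each peak counted for the gene with the nearest TSS only (18 of 73, 24.7%, Fisher's exact test, adjusted p = 0.206).

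Genes of chromatin regulators also stood out. Of the insulator and architectural proteins, which bind domain borders, 11 of 17 had a promoter peak (64.7%, 41.3 to 82.7, Fisher's exact test, adjusted p = 0.00153). They included Chro (22878720 to 22879064 on 3L, signal 2663), Cp190 (15275184 to 15275588 on 3R, signal 2158), pzg (21285688 to 21286085 on 3L, signal 645) and M1BP (8731875 to 8732140 on 3R, signal 621). Of the Polycomb and Trithorax group, which maintain repressed and active gene states, 11 of 22 had one (95% interval 30.7 to 69.3%, Fisher's exact test, adjusted p = 0.0261), among them ph-p, brm (15982837 to 15983183 on 3L, signal 1996), E(z) (10637814 to 10638211 on 3L, signal 1645) and mor (15972923 to 15973166 on 3R, signal 698). Of the cell cycle genes, 13 of 27 had one (48.1%, 30.7 to 66.0, Fisher's exact test, adjusted p = 0.0183), among them Dp (13223196 to 13223514 on 2R, signal 1084), CycE (15746900 to 15747144 on 2L, signal 670), Mcm2 (8264715 to 8264983 on 3R, signal 496) and dup (15380626 to 15380782 on 2R, signal 396). The Polycomb and Trithorax call and the cell cycle call ended with genes matched on their number of TSSs (permutation within strata, adjusted p = 0.0773 for each) and with the stronger 2519 peaks (6 of 22 and 5 of 27, Fisher's exact test, adjusted p = 0.296 and 0.767). The former also ended at a TSS distance of 1000 bp (11 of 22, Fisher's exact test, adjusted p = 0.0776), and the latter at 250 bp (9 of 27, 0.205) and without replicate 1 (9 of 27, 0.329). With genes of divergent pairs left out, a setting chosen after the data were seen, 25 of 37 cytoplasmic ribosomal protein genes passed (67.6%, Fisher's exact test, adjusted p = 8.32e-13), and the mitochondrial ribosomal list (3 of 15, 0.677) did not, with its odds ratio at 1.82 against 3.71 before. The insulator (3 of 7, Fisher's exact test, adjusted p = 0.183), Polycomb and Trithorax (4 of 10, 0.167) and cell cycle lists (5 of 14, 0.167) did not pass either, with fewer genes tested, while their odds ratios were 5.05, 4.50 and 3.76, against 5.70, 3.22 and 3.00 with all genes.

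Genes of single tissues and of body patterning did not carry promoter peaks more often than other genes. Of 8 Hox genes, which set segment identity, 0 had one (Fisher's exact test, adjusted p = 0.384), although 6 IDR-thresholded summits lay inside Antp, 2 inside Abd-B and 1 inside pb, counts looked up after the data were seen. Among neural progenitor genes 3 of 23 had a promoter peak (Fisher's exact test, adjusted p = 0.477): numb (9449407 to 9449750 on 2L, signal 897), brat (19133601 to 19133696 on 2L, signal 331) and scrt (3983404 to 3983753 on 3L, signal 145). The counts were 2 of 22 for neuronal differentiation genes (Fisher's exact test, adjusted p = 0.267), 2 of 25 for segmentation and patterning (0.212), 1 of 17 for epidermis and cuticle (0.212), 1 of 10 for trachea (0.585), 2 of 18 for gut, fat body and hemocytes (0.458), 2 of 10 for glia (1) and 7 of 24 for muscle (0.585). The Notch pathway (8 of 24, 0.477), ecdysone response (5 of 18, 0.822), heat shock (8 of 27, 0.585) and proteasome lists (13 of 48, 0.678) did not pass either. Without replicate 3 the counts were 1 of 8 for Hox genes, 3 of 17 for epidermis and cuticle, 2 of 10 for trachea and 1 of 18 for gut, fat body and hemocytes, with adjusted p of 0.812, 0.731, 1 and 0.128 (Fisher's exact test). The neuronal differentiation list was below other genes with matching on the number of TSSs (adjusted p = 0.0200), and the segmentation list without replicate 3 (1 of 25, Fisher's exact test, adjusted p = 0.0173).

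Chemoreceptors and histones lay at the low end. Of 179 odorant, gustatory and ionotropic receptor genes, only Ir60e had a promoter peak (24531384 to 24531733 on 2R, signal 192). The share was 0.559% (0.0987 to 3.10, Fisher's exact test, adjusted p = 5.09e-19). Ir60e belongs to a head-to-head pair. With each peak counted for the gene with the nearest TSS only, 0 of 179 had a promoter peak. Of 111 replication-dependent histone genes, 0 had one (0 to 3.35%, Fisher's exact test, adjusted p = 9.80e-13). These histone genes lie in a tandem repeat where reads cannot be placed uniquely, so their count is uncertain. A count of 0 could arise there whether or not the protein was bound. The test also counts copies of the repeat as separate genes, so it does not show that these genes lack the protein. With divergent pairs left out, 0 of 27 had a promoter peak against 13.4% of other genes, and with fewer genes tested the list did not pass (Fisher's exact test, adjusted p = 0.167).

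**Figure D3:**
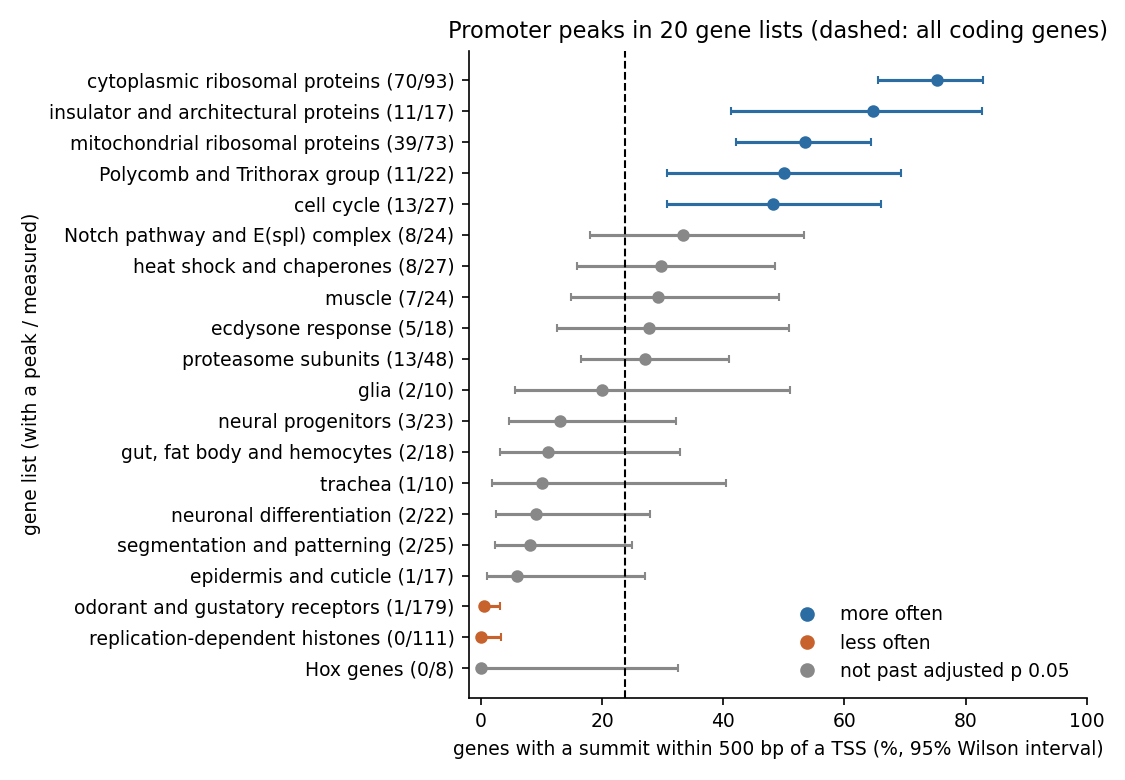
Percent of genes in each of 20 lists with an IDR-thresholded summit within 500 bp of a TSS (horizontal axis), with 95% Wilson intervals and the number with a peak over the number measured. The dashed line is all coding genes, 23.7%. Past an adjusted p of 0.05, 5 lists lay above it (blue) and 2 below it (orange). Of the latter, the histone list is uncertain, since reads in its repeat cannot be placed uniquely.

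Promoter peaks were more frequent at head-to-head gene pairs. Of the 3309 genes with a promoter peak, 2102 (63.5%, 61.9 to 65.1) had a coding TSS on the opposite strand within 1 kb upstream, against 2811 of 10636 genes without one (26.4%, 25.6 to 27.3), an odds ratio of 4.85. A peak between 2 such genes counts for both. Counted for the gene with the nearest TSS only, a setting chosen after the data were seen, the shares were 50.4% and 32.2%, with an odds ratio of 2.15 (Fisher's exact test, two-sided, p = 1.13e-61).

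Stronger peaks lay at start sites more often. With the IDR-thresholded list split by signal into 4 parts of nearly equal size, from the strongest to the weakest, 65.2% (62.5 to 67.7), 54.4% (51.7 to 57.2), 47.3% (44.6 to 50.1) and 41.5% (38.8 to 44.3) of summits lay within 500 bp of a TSS. The mean signal rank of promoter peaks was 2270 and that of other peaks 2791 (permutation test, two-sided, p = 1e-05, the smallest 100000 permutations can give).

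Sequence at the summits differed from that of the flanks. Windows of 201 bp on the summits had a mean GC content of 34.9% ± 6.90 (SD over 5038 peaks), against 43.7% ± 7.16 in flanks centred 600 bp away, and the summit was the lower in 80.9% of peaks. Of 26 motifs, 12 were more frequent at summits than in flanks and 6 were less frequent (exact sign test, adjusted over the 26). The counts were 3 and 5 at peaks over 500 bp from a TSS, 9 and 11 at promoter peaks against coding TSSs without one, and 9 and 2 against a control matched on GC content and TSS distance, where 0 of the 6 remained less frequent past the threshold and the E-box CAGCTG became more frequent (ratio 1.65). The DRE, bound by the promoter factor Dref and the insulator protein BEAF-32, was present in 4.29% of summit windows (3.76 to 4.88) and 0.576% of flanks (exact sign test, adjusted p = 8.08e-34). The CTCF core, the site of the insulator protein CTCF, was present in 2.66% (2.25 to 3.14) and 0.595% (exact sign test, adjusted p = 3.68e-18), and Ohler motif 7, a core promoter element, in 13.4% (12.5 to 14.4) and 5.86% (adjusted p = 4.27e-35). The BEAF-32 core (31.2% against 22.2%) and the homeodomain site TAATTA (19.0% against 10.9%) were more frequent too, with adjusted p of 8.98e-23 and 1.13e-26. The GAGA repeat (2.24% against 4.59%, exact sign test, adjusted p = 2.70e-11) and the GT repeat (4.23% against 10.0%, adjusted p = 2.41e-29) were less frequent.

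The choice of control changed several of these motifs. Against that matched control, chosen after the data were seen, the DRE (4.29% against 1.15%), the CTCF core (2.66% against 0.0992%) and Ohler motif 7 (13.4% against 4.80%) remained more frequent (Fisher's exact test, adjusted p = 3.40e-22, 6.78e-33 and 2.20e-51). There the homeodomain site did not differ past the threshold (19.0% against 18.1%, Fisher's exact test, adjusted p = 0.313), nor did the GAGA repeat (2.24% against 1.97%, adjusted p = 0.434) or the GT repeat (4.23% against 3.65%, adjusted p = 0.246). Motif 1, bound by M1BP, was more frequent at summits than in flanks (1.57% against 0.328%, a ratio of 4.79) and than in the matched control (0.377%, Fisher's exact test, adjusted p = 2.58e-09), and its ratio to the flanks was 2.86 with the stronger 2519 peaks, 3.81 without replicate 1 and 9.8 without replicate 3. At promoter peaks against windows centred on coding TSSs without a peak, the ratios were 1.35 for the DRE (7.81% against 5.77%), 1.15 for the BEAF-32 core, 1.88 for Ohler motif 7, 2.14 for the homeodomain site (20.2% against 9.45%), 4.69 for the CTCF core and 0.733 for Motif 1. Counted per gene, summits lay a median of 135 bp upstream of the TSS, and these control windows lay on it. The comparison therefore does not separate the effect of a peak from that of position, above all for elements at a fixed distance from the TSS.

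Among all 8192 distinct 7-mers, 1518 were more frequent at summits and 3127 less frequent (exact sign test, adjusted p under 0.05). Against the control matched on GC content and TSS distance the counts were 463 and 418. The 10 with the largest ratio, present in at least 2% of windows, were ACTATCG, CAGTGTA, CTATCGA, ATCGATA, AACTATC, AGTGTAG, CACTGAG, AGGGATG, ACACTGA and CACTGTA, and all 10 remained more frequent against the matched control. Several of the 10 overlap in sequence, and all were picked on the same summit windows, so they are not separate results. CAGTGTA, CACTGAG, ACACTGA and CACTGTA hold CAGTG on 1 strand or the other, and ACTATCG and CTATCGA hold CTATCG. The 10 differed by the position of the peak. ATCGATA was present at 15.6% of promoter summits (14.2 to 17.0) and 1.95% of others (1.47 to 2.58), a 7.99-fold difference (Fisher's exact test, adjusted p = 1.11e-70). ACTATCG was present at 10.1% and 1.12% (Fisher's exact test, adjusted p = 1.12e-47). This contrast also sets promoter sequence against other sequence. The DRE, which holds ATCGATA, was present in 5.77% of windows on coding TSSs without a peak. CAGTGTA was present at 4.61% of promoter summits (3.87 to 5.48) and 9.41% of others (8.31 to 10.6; Fisher's exact test, adjusted p = 6.43e-11), and CACTGAG at 2.93% and 7.67% (adjusted p = 1.10e-13). Away from start sites, ATCGATA was no more frequent at summits than in flanks (1.95% against 2.22%, exact sign test, adjusted p = 0.249), whereas CAGTGTA was (9.41% against 1.68%, adjusted p = 1.14e-31). The DRE was likewise at its flank level there (0.456% in both), as were Ohler motif 7 (5.64% against 5.39%) and the BEAF-32 core (21.1% against 21.9%), and the CTCF core was not (3.28% against 0.643%, exact sign test, adjusted p = 4.51e-10).

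**Figure D4:**
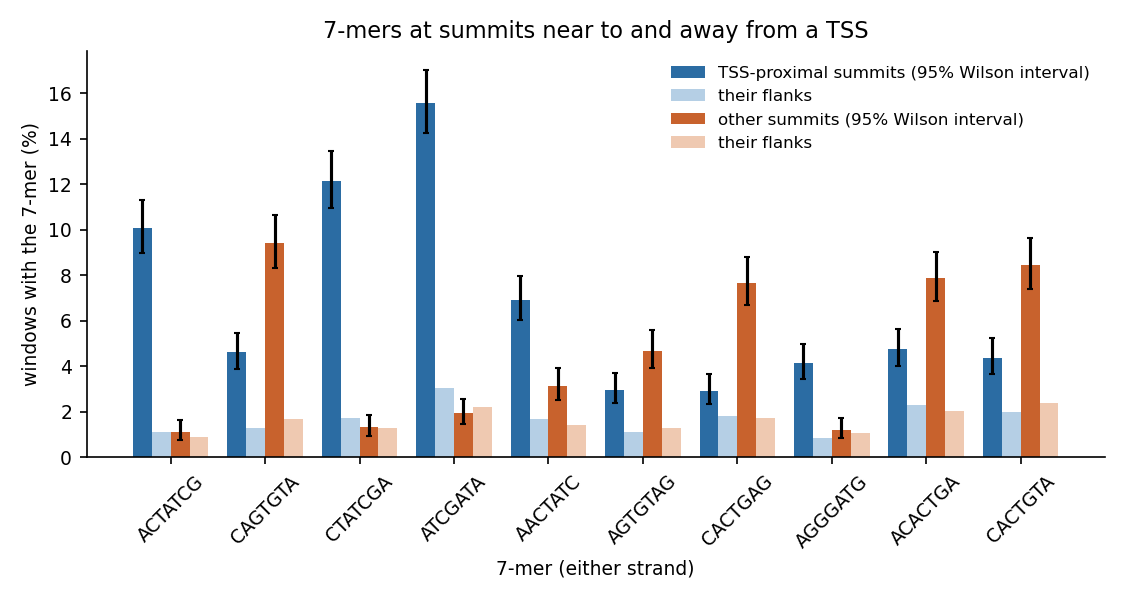
Percent of 201 bp windows (vertical axis) that held each of 10 named 7-mers on either strand, at summits within 500 bp of a TSS (dark blue) and other summits (dark orange), with 95% Wilson intervals, and in their flanks (light). ATCGATA reached 15.6% at promoter summits and 1.95% at others, while CAGTGTA reached 4.61% and 9.41%.

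The tagged gene itself, CG43347 (FBgn0263072), spans 10602641 to 10620190 on the minus strand of the X chromosome. Within 5 kb of it lay 4 IDR-thresholded peaks, and within 20 kb 6. The peak at 10620674 to 10621023 (rank 2235, signal 280) had its summit at −659 bp from the TSS of CG43347. The other 3 lay at its 3' end, nearest to the TSS of CG1628: 10601733 to 10601925 (rank 1235, signal 436), 10600638 to 10600818 (rank 1796, signal 333) and 10602353 to 10602702 (rank 4186, signal 156). Each of the 4 was present in both replicates' lists. The peaks do not bear on whether the tag worked.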

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

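Alternatives that used the matched control, left out divergent pairs, took 1 gene per peak for divergent promoters took pooled peaks as background, took summits outside TSS regions alone or took full or pooled lists for the arms were chosen after the data were seen. Of 460 recomputed values, 374 kept their direction and side of the threshold or stayed within their range, and 86 did not, of which 20 turned direction. The stricter list gave a Spearman rho of 0.779 and 2061 genes with a promoter peak, the latter because fewer peaks entered. The number of gene lists above other genes fell from 5 to 3 with the stricter list, to 3 with strata of TSS number and to 1 (cytoplasmic ribosomal proteins) with divergent pairs left out, where fewer genes were tested. Peaks over 500 bp from a TSS gave 3 motifs above the flanks. The count of enriched sequences was 558 with 6-mers, of which fewer exist, and 463 with the control matched on GC content and TSS distance. Ratios turned direction for the BEAF-32 core (0.965), Motif 1 (0.571) and Ohler motif 5 (0.733) at peaks over 500 bp from a TSS, none past the threshold. Against TSSs without a peak they did so for Motif 1 (0.733), Ohler motif 6 (0.731), Ohler motif 5 (0.969) and the TATA box (0.580). Of these, only Motif 1 and the TATA box passed the threshold. Against the matched control they did so for the GAGA repeat (1.14), TATA box (0.809), E-box CAGCTG (1.65), GT repeat (1.16) and poly(A) tract (0.930). There only the TATA box and the E-box passed it. The other turned ratios named here did not differ from their control past the threshold. Windows on TSSs and on summits differ in position, which alone can set the ratio of elements tied to the TSS. Among summits outside TSS regions alone, introns turned to above random (70.8%), other exons gained a call (1.70%) and 5' UTRs lost theirs (0.829%), since the larger TSS share no longer entered. Arm ratios with the stricter list were 1.06 (2L), 0.943 (3L) and 1.09 (X), with these calls lost. Without replicate 1 or 3 they were 1.07 and 1.05 (2L), 0.947 and 0.953 (3L) and 1.11 and 1.07 (X), and each of these arms lost its call without replicate 3, as 3L did without replicate 1. Arm 3R had 1.00 without N bases, just under its share. In the full lists of replicates 1 and 3 and the pooled peaks outside the IDR-thresholded list, X (0.879, 0.826, 0.805) and 3L (1.02, 1.07, 1.07) turned direction, and 2R (0.971, 0.941, 0.933) and 3R (1.05, 1.07, 1.09) gained a call. The cause was not tested for the rho, the motif ratios or the arms. Without replicate 1 the cell cycle list lost its call (odds ratio 1.84), and the Zelda motif fell below the flanks past the threshold (ratio 0.688). Without replicate 3 Zelda did so too (0.618), the segmentation list was called below other genes (odds ratio 0.167), Su(H) lost its call (0.882), Motif 1 rose to a ratio of 9.8, and the chromosome 4 ratio was 0.276. The depth of the libraries is unknown, so what it limits could not be measured.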

Other observations

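All tests in this part were chosen only after the result was seen. Further families were looked up among the promoter peaks of protein-coding genes. Of 29 Mediator subunits, which link activators to RNA polymerase II, 13 had a promoter peak (44.8%, 28.4 to 62.5, Fisher's exact test, adjusted p = 0.0348 over 15 families), led by MED27 (5654835 to 5655166 on 3R, signal 1201) and MED30 (654090 to 654389 on 3L, signal 1038). Of 29 TFIID and RNA polymerase II genes, 13 had one as well (Fisher's exact test, adjusted p = 0.0348), led by Polr2B (14125510 to 14125861 on 3R, signal 1118) and Polr2H (21728629 to 21728945 on 3L, signal 1032). MED27, MED30, Polr2B and Polr2H each belong to a head-to-head pair, where a peak can count for both genes. The values for all 15 families come from the main setting alone, and several of the 20 lists above lost their calls in other settings. Aminoacyl-tRNA synthetase genes (13 of 33, Fisher's exact test, adjusted p = 0.0874), initiation factors (14 of 44, 0.272) and respiratory chain genes (21 of 87, 0.900) did not pass. Cuticle proteins had 0 of 117 (Fisher's exact test, adjusted p = 3.15e-13), cytochrome P450 genes 6 of 85 (6.99e-04), Jon and Try serine proteases 0 of 31 (0.00153) and odorant binding proteins 2 of 51 (0.00105).

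The hexamer CTATCG lay under 595 IDR-thresholded summits and the pentamer CAGTG under 2313, with 244 summits holding both against 273 for independent placement (Fisher's exact test, p = 0.0110). Within promoter peaks the count was 207 against 214 (Fisher's exact test, p = 0.515), and in other peaks 37 against 44.8 (p = 0.107). Peaks of a replicate alone were, as above, those without a match by reciprocal overlap. Many of those of replicate 1 still overlapped a peak among the strongest 5038 of replicate 3, and those of replicate 3 may do likewise. CTATCG was present in 17.9% of the peaks of replicate 1 alone (16.3 to 19.7) and 7.93% of those of replicate 3 alone (6.82 to 9.21). Of the same peaks, CTATCG was present in 4.73% and 3.39% of those over 500 bp from a TSS and in 26.6% and 16.2% of those nearer. CAGTG was present in 44.1% (42.0 to 46.3) and 46.7% (44.5 to 48.9), and the longer CAGTGTA in 4.87% (4.01 to 5.91) and 8.80% (7.62 to 10.1). Among those over 500 bp from a TSS, CAGTGTA was present in 7.93% of 782 and 9.85% of 1269, and among those nearer in 2.86% and 6.88%.

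Few IDR-thresholded summits lay in coding sequence, and low GC content was weighed as a candidate explanation. Random positions matched on GC content lay in coding sequence in 5.79% of 4627 cases outside TSS regions (5.15 to 6.50), against 0.373% of 2412 summits (0.196 to 0.708), which argues against base composition as the whole cause. Calling or control normalization that keeps peaks of any strength out of coding sequence was weighed through the 5000 weakest pooled peaks, of which 14.4% (13.4 to 15.4) lay there, against 13.7% in random placements. The weakest calls were thus not kept out of coding sequence, but they do not decide for stronger peaks. Their share at start sites was near random too (14.9% against 13.6%). The pooled list runs down to a −log10 q of 0.0461, so many may be background. Of all 24962 pooled peaks outside the IDR-thresholded list, 9.96% (9.59 to 10.3) lay in coding sequence, below the 13.7% at random. The bound, 0.5 of the random share, was set after the value was known. A first bound (any share below the 15.7% of random positions outside peaks) would have read the same value as support for such an exclusion. No biological explanation was tested.

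Replicate 1 had the higher promoter share, and weak peaks near the threshold, where ranking is noise, were weighed first as a candidate explanation. The difference was 6 percentage points among the 500 strongest peaks (Fisher's exact test, adjusted p = 0.0461 over 7 list sizes) and 8.1 among the 1000 strongest (adjusted p = 1.65e-04), which argues against weak peaks alone, narrowly at the smaller size. Unequal recovery of AT-rich fragments cannot be told apart from other sources. Within bins of GC content over windows of 801 bp the difference was 9.71 points (SE 0.988, 7.77 to 11.6), against 9.92 without bins, but GC content there was 40.5% at promoter peaks and 41.0% at others, too close for such bins to move a promoter share. Windows of about 0.5 times that length gave 9.72 points, with 37.4% at promoter peaks and 38.8% at others, and windows of 201 bp gave 9.75 points, with 35.2% and 35.1%. An earlier test had counted as support for unequal recovery: summits of replicate 1 alone had a mean GC content of 36.8%, against 35.3% for replicate 3 alone. A difference in depth or in precipitation between the libraries was not tested and stays open, and no biological explanation was tested.

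Chromosome 4 held few peaks, and its gene density was weighed as a candidate explanation. Of its 80 protein-coding genes 1 had a promoter peak (1.25%, 0.221 to 6.75), against 23.9% of 13865 elsewhere (Fisher's exact test, p = 1.57e-08), which argues against gene density. Among pooled peaks outside the IDR-thresholded list, chromosome 4 had 5 where 251 were expected, a ratio of 0.0199. The full lists had 43 peaks there in replicate 1 (ratio 0.142) and 11 in replicate 3 (0.0364), so the extent differed between replicates. Weak peaks were few on the arm in each of these lists. Calling or control normalization that keeps peaks of any strength off chromosome 4 may account for the pattern. An arm with few bound sites could hold few weak peaks too, so these counts cannot tell the explanations apart. No biological explanation was tested.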
